A study of Homo sapiens with 2 samples.

How the data were processed

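Nascent RNA was measured by global run-on sequencing (GRO-seq) in BJ cells, an established human skin fibroblast line, grown without treatment. In GRO-seq, isolated nuclei are given a brominated nucleotide so that RNA polymerases already engaged on a gene extend their transcripts, and the labelled RNA is captured with an antibody and sequenced. The read density over a gene therefore reports how much polymerase was transcribing it, not the amount of mature mRNA. Per the labels' protocols, nuclei were run on for 5 min at 30 °C in the presence of sarkosyl, the RNA was fragmented by base hydrolysis, and libraries were made with a small RNA kit from 2 biological replicates. The cells grew in medium with 10% serum.

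The deposited table holds FPKM values (fragments per kilobase of gene, scaled to the size of the library) for 12353 Ensembl gene identifiers in 2 columns, made by the authors. Bowtie2, HTSeq and the genome build hg19 are named in the submitters' processing notes, without versions. The length each count was divided by, the read total used for scaling, the treatment of reads that map to several places, and the use of strand in the counting are not given in the sources used here. The replicates were not pooled. No value was 0 in either column and the lowest were 0.29 and 0.27, so the table holds only genes above some minimum, and a gene with no value is described here only as having none. The column names end in a and b, whereas the labels number the replicates, so the columns could be tied to the group but not to a replicate number. They are called library a and library b.

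Depth is unknown. FPKM was not given with counts, and ratios between the columns did not pile up at a common value from which the relative depth could be read: the fullest of the narrow ratio bins held 11 of 3328 genes over FPKM 20, and 1.23 bins as full would be expected by chance. So no counting interval or detection floor is given. The error given with each value is the SD over the 2 libraries. An SD of 2 values is itself very uncertain, so a small one does not show that a gene's value is known closely. The summed FPKM, 396182 in library a and 405850 in library b, is not a read total.

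Identifiers were paired with current gene symbols through an Ensembl name table, which matched 12202 of the 12353. The other 151 stayed in the background under their identifiers and are not named. No symbol occurred more than once. A RefSeq table on GRCh38 gave the gene class and the order of genes along the chromosomes. Since the values were made on hg19, no length was taken from that table, gene length was not examined, and genomic positions are not given. Its gene spans on GRCh38 were used to find genes that hold a small RNA gene. That table has no strand column, so neighbouring genes were not divided by orientation.

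All samples belonged to 1 group, so no comparison between conditions was possible and no p-value was computed. An exact sign-flip test of 2 replicates cannot go below p = 0.5. Instead, 34 gene lists, 9 contrasts between lists and 15 gene pairs were fixed before the data were examined. For each list with at least 3 measured members, the median over members of log2(FPKM + 0.1), averaged over the libraries, was placed among the medians of 10000 random lists of the same size drawn from all 12353 genes. A list was called high at percentile 97.5 or more and low at 2.5 or less. The percentile describes these libraries, since genes are not independent replicates. With 31 lists placed, 1.55 calls would be expected by chance. Contrasts were treated alike, with 10000 random pairs of lists. Differences between the libraries, as log2 of (FPKM + 0.1) in b over a less the median of all genes, were placed among 10000 random lists matched on level in 20 bins. Of the 610 listed genes with a value, 15 were in more than 1 list.

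Genes are named by a rule set in advance, namely the 20 highest by mean FPKM, up to 3 highest and 1 lowest of each list, the 10 with the largest difference between libraries among genes at FPKM 1 or more in both, and the members of the pairs. Some genes this rule selects, 1 of the planned pairs and 1 of the lists are not reported here. Other names are marked as chosen after their values were seen. Genes of the Y chromosome and XIST were left out of the naming and of the gene table.

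The list procedure was tested on simulated data made from the real gene means and the spread between the libraries, with lists of 20 genes and 200 genes shifted at a time among 12353. All genes were given 1 common spread. The measured SD of the log2 difference fell from 0.310 in the lowest of 5 level classes to 0.154 in the highest. Lists of other sizes were not simulated, so the rates below do not carry over to short lists. For list levels, 86% of lists shifted by a fold of 2 and 100% of those shifted by a fold of 4 were called high, against 2% of unshifted lists. For differences between libraries, 56.7% of lists shifted upward by a fold of 1.1 were called high, and 100% of those shifted by 1.2. Of 30 unshifted lists 6.67% were called high. Downward shifts were not simulated and low calls were not counted. The alternatives were pseudocounts of 0.01 and 1, a minimum mean FPKM of 1, quantile normalization, the mean in place of the median, and each library alone. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.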

Results

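Nascent RNA levels were measured by GRO-seq in untreated BJ fibroblasts, with 2 libraries that form a single group. Values were obtained for 12353 genes, of which 12000 were protein-coding in RefSeq and 61 were long noncoding. They covered 59.8% of the 20056 RefSeq protein-coding genes. The median FPKM was 11.8 in library a and 11.7 in library b, with quartiles (25% and 75% of genes) at 6.29 and 22.2 in library a and at 6.13 and 22.1 in library b. Values below are means ± SD over the 2 libraries (n = 2). The read depth behind them is unknown, and a p-value was not computed, because the series has no second condition.

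The first question was how closely the replicates measured the same levels. The 2 libraries ranked the genes almost alike, with a Spearman rho of 0.986 and a Pearson r of 0.988 on the log2 scale across genes, which are not independent replicates. The median gene differed by a factor of 1.097 between libraries. The difference was smaller for strongly transcribed genes, with genes split into 5 equal classes by level: the median factor was 1.15 in the lowest class (mean FPKM up to 5.28) and 1.07 in the highest. Only 267 genes (2.16%) differed by more than 1.5-fold and 12 by more than 2-fold. The 10 largest differences among genes at FPKM 1 or more were in modestly transcribed genes. TMEM205 stood at 3.74 in library a and 12.1 in library b, and KIF17, a kinesin motor, at 1.49 and 3.63. The other 8 were higher in library a. They were GNG13, a G protein gamma subunit (17.2 against 6.05), CPQ (4.41 against 1.73), MFSD2A, a lipid transporter (4.31 against 1.90), GPR21 (9.74 against 4.41), NOMO1, which has near-identical copies (3.51 against 1.59), the bitter taste receptor gene TAS2R14 (4.64 against 2.13), PLN, the regulator of the calcium pump of muscle (5.14 against 2.38), and PARP11 (2.70 against 1.24).

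**Figure D1:**
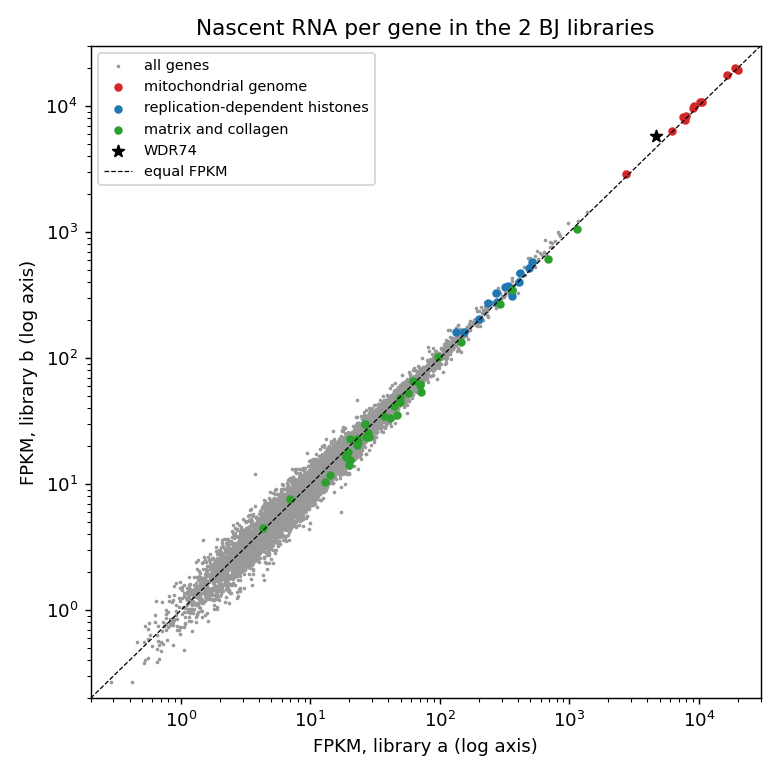
FPKM of each gene in library a (x axis) and library b (y axis), both on log axes, with 1 point per gene, 3 gene lists in colour, WDR74 as a star and a dashed line at equal values. Points follow the line (Spearman rho 0.986) and spread more widely at low FPKM, while the mitochondrial genes and WDR74 sit above all other genes.

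Of the gene lists, matrix and contractile genes stood higher in library a and histone genes higher in library b. Among 34 measured matrix genes 28 lay below the median shift of all genes and 6 above, with a median log2 difference of -0.10 (percentile 0.01 among level-matched lists). Contractile genes had a median of -0.10 (percentile 0.13), with 3 of 15 members above 0. Replication-dependent histone genes lay on the other side, at 0.16 (percentile 99.7), with 12 of 15 members above 0. These shifts are 1.07-fold, 1.07-fold and 1.12-fold between libraries. The histone shift came to 0.0049 after quantile normalization (percentile 53.5), and with the list mean in place of the median the contractile and histone lists were no longer called. The other 28 lists with at least 3 measured members were not called, although list means called ribosomal protein genes high (percentile 99.59) and splicing factors low (0.95).

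Mitochondrial genes held a large share of the summed FPKM. That is not a share of reads, because each count is divided by a gene length. A total of 300 genes reached a mean FPKM of 100 and 18 reached 1000, while 12256 stood at 1 or more in both libraries. The 10 highest genes, all mitochondrial, held 29.8% of the summed FPKM in library a and 30.2% in library b. Among nuclear genes alone the 10 highest held 5.12% and 5.71% and the 100 highest 17.4% and 18.7%. All 12 measured protein-coding genes of the mitochondrial genome, which encode respiratory chain subunits, were among the 20 highest named genes. Together they held 32.1% of summed FPKM in library a and 32.4% in library b. The highest were MT-ND6 (19670 ± 433), MT-ND5 (19557 ± 583) and MT-CYB (17145 ± 765), and the lowest was MT-ATP6 (2820 ± 98.6). Between them stood MT-ND4 (10718 ± 189), MT-ND2 (10497 ± 349), MT-ND1 (9578 ± 487), MT-CO2 (9320 ± 475), MT-CO1 (8159 ± 224), MT-ND4L (7845 ± 436), MT-CO3 (7775 ± 80.2) and MT-ND3 (6266 ± 36.3). MT-ND6 lies antisense to the other mitochondrial genes named here, and the use of strand in the counting is not given in the sources used here.

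The other 8 of the 20 highest named genes were nuclear. WDR74, a ribosome assembly factor, had the highest nuclear value, 5218 ± 768, which was 446 times the median gene, and its annotated span also holds the U2 small nuclear RNA gene RNU2-2. It was followed by the cytoskeletal actin gene ACTG1 (1410 ± 44.9), the matricellular genes CCN1 (1194 ± 42.1) and THBS1 (1105 ± 54.9), ID1 (884 ± 59.7) and ID3 (775 ± 55.8), which encode inhibitors of helix-loop-helix transcription factors, the transcriptional coregulator CITED2 (809.5 ± 52.7) and ACTB (750.3 ± 18.2). Of the 100 highest identifiers, 22 had no current symbol and are not named.

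The second question was which gene programmes had the highest FPKM. Random lists were not matched on gene length. Levels and contrasts of lists therefore also depend on the length used in the FPKM, which is not given in the sources used here. Genes of fibroblast identity were transcribed well above the typical gene. Extracellular matrix genes had a median FPKM of 32.0, 2.73 times the median of all genes and above all 10000 random lists, and 34 of 37 had a value. THBS1, COL1A1 (649 ± 48.1) and COL1A2 (353 ± 7.53), the chains of type I collagen, led the list, and TGFBI was lowest at 4.41 ± 0.141. Mesenchymal identity genes had a median of 28.6 (percentile 99.97), with 23 of 26 measured. The intermediate filament gene VIM stood at 539 ± 9.28, S100A6 at 332 ± 4.22 and S100A4 at 186 ± 8.55, whereas the transcription factor gene OSR1 was at 3.13 ± 0.905. All 15 contractile genes had values, with a median of 72.8 (above all random lists). The list was led by the myosin light chain gene MYL6 (446 ± 14.5), the tropomyosin gene TPM2 (225 ± 16.5) and MYL9 (191 ± 5.81), and calponin CNN1 was lowest at 7.71 ± 2.05.

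Of the markers of other cell types, several lists had few measured members. Genes of mature smooth muscle formed the only list called low, with a median of 5.01 over 6 of 10 members (percentile 1.88). Across the 31 lists placed, 1.55 calls, high or low, would be expected by chance, so 1 low call may be due to chance. Smoothelin, SMTN, was at 31.8 ± 0.255, MCAM at 9.21 ± 0.976, SYNM at 7.02 ± 0.00707 and MYOCD, the smooth muscle coactivator, at 1.28 ± 0.170. Epithelial and keratinocyte genes had values for 8 of 23 members (percentile 0.935 for that number among random lists of protein-coding genes), with a median of 5.89 that was not called (percentile 2.58), although it was with library b left out (2.06). It came to 3.30 with library a left out, 8.99 with list means and 18.285 with a minimum mean FPKM of 1. The simple-epithelium keratin genes KRT18 (76.7 ± 0.679) and KRT8 (29.3 ± 1.48) and the epidermal KRT10 (38.2 ± 3.87) were its highest members and filaggrin, FLG, its lowest at 0.680 ± 0.141. The endothelial list had 4 of 15 members measured (percentile 0.65 for the number), the VEGF receptor gene FLT1 (8.61 ± 0.396), CLDN5 (7.88 ± 0.141), ESAM (3.56 ± 0.226) and ROBO4 (2.78 ± 1.25). The leukocyte list had 3 of 17 (percentile 0.015), CD74 at 11.8 ± 2.47, CD4 at 10.7 ± 1.73 and CSF1R at 8.66 ± 1.15. The neuronal list had 4 of 14 (percentile 1), led by SYN1 (8.29 ± 1.04), SYT1 (5.90 ± 0.566) and ELAVL3 (4.22 ± 0.926), with RBFOX3 at 4.06 ± 0.141. The median levels of these 3 lists were 5.72, 10.7 and 5.06, none of them called (percentiles 6.54, 43.8 and 5.19, the first 3.98 with list means). Of the melanocyte genes, 5 of 10 had values, with PMEL at 22.4 ± 2.23, the regulator MITF at 9.90 ± 1.44, MLANA at 4.53 ± 0.750 and SLC45A2 at 2.79 ± 0.148, and a median that was not called (4.53, percentile 3.18), although it was with library b left out (2.01). It came to 5.005 with library a left out and 6.93 with list means. None of the 15 hepatocyte and pancreas genes had a value, against 59.8% of all protein-coding genes.

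**Figure D2:**
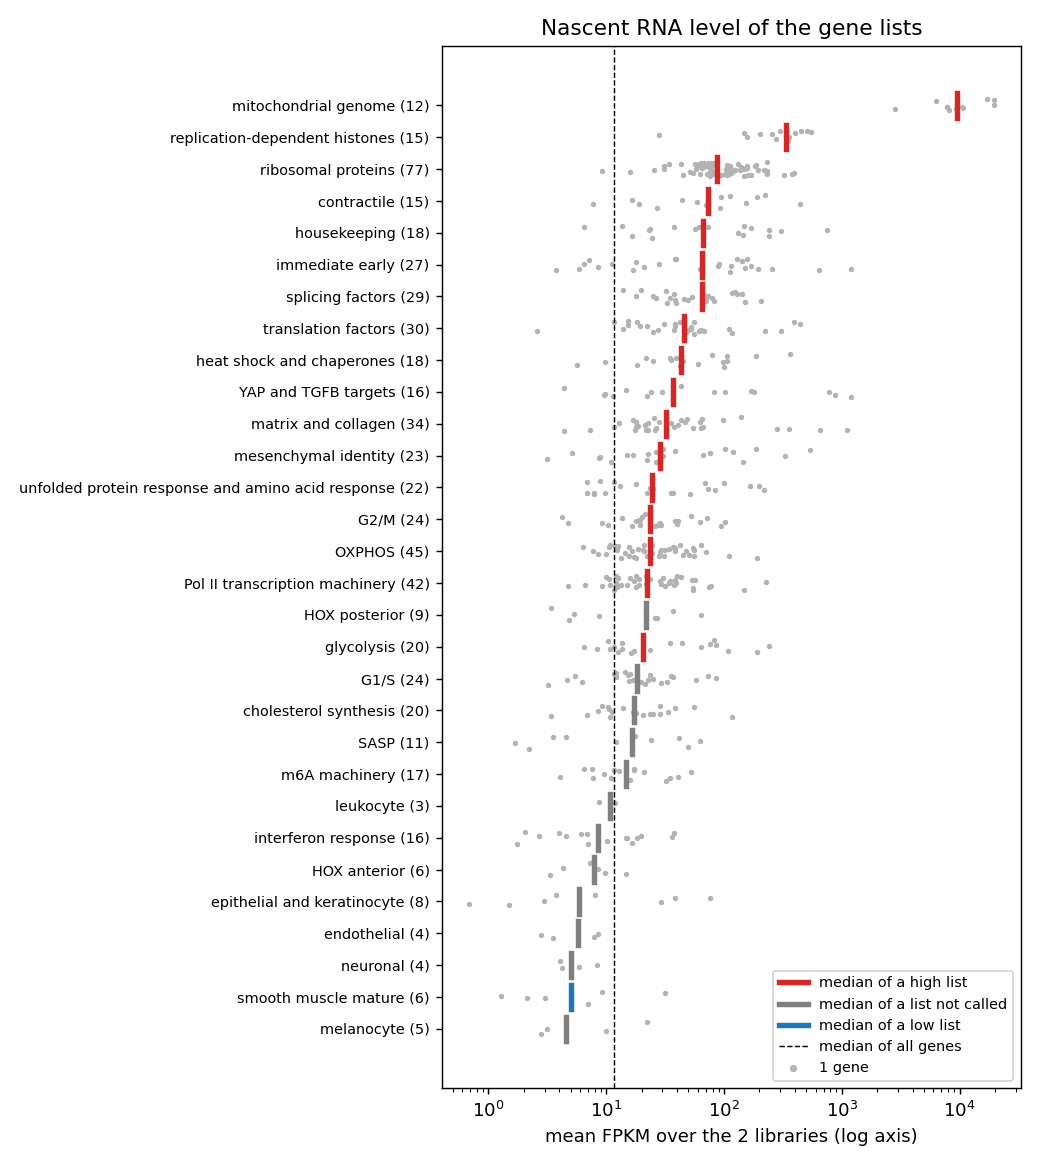
Mean FPKM over the 2 libraries (x axis, log axis) of each measured member of 30 gene lists (rows, with the number of measured members), with the list median as a thick bar coloured by its call and the median of all genes, 11.7, as a dashed line. The mitochondrial, histone and ribosomal protein lists have the highest medians (9449, 335 and 88.1), and most lists of other cell types lie left of the dashed line.

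The planned contrasts put these differences in numbers. Each is a difference between list medians of log2(FPKM + 0.1), averaged per gene over the libraries, so it need not lie between the single-library values. Folds of contrasts, here and below, are taken from that difference and need not equal the ratio of the FPKM medians. Matrix genes stood 2.51 log2 units above epithelial and keratinocyte genes (2.58 in library a, 2.48 in library b), a 5.69-fold difference of medians (percentile 99.99 among random pairs of lists). Mesenchymal identity genes were 5.29-fold above endothelial genes (percentile 99.8) and contractile genes 15.4-fold above mature smooth muscle genes (above all 10000 random pairs). Mesenchymal genes were 2.66-fold above the 3 leukocyte genes (log2 difference 1.41, against 1.49 in library a and 1.51 in library b), which was not called (percentile 92.4) but was with list means (log2 difference 1.77, percentile 97.91). Matrix genes lay 2.10-fold below housekeeping genes (percentile 1.23). With list means this became a log2 difference of -0.76, which was no longer called (percentile 3.74). The SD of the 2 single-library values was at most 0.105 log2 units for each of these contrasts. Genes without a value do not enter these medians.

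Genes of growth and basic cell machinery were called high in 6 lists. Ribosomal protein genes had a median of 88.1, with 77 of 78 measured and 76 of them above the median of all genes. RPL41 (394 ± 9.42), RPL10A (377 ± 1.72) and RPL12 (324 ± 4.86) were highest, and RPL17 was lowest at 9.31 ± 1.76. Their median was 3.74-fold above that of nuclear-encoded oxidative phosphorylation genes (percentile 100), whose own median was 23.5 (45 of 45 measured). In that list NDUFB10 was at 192 ± 11.4, ATP5MC1 at 110 ± 0.445, NDUFV2 at 70.3 ± 1.36 and NDUFA10 at 6.36 ± 0.460. Translation factors had a median of 45.4, from the helicase gene EIF4A2 (446 ± 9.98), EIF1 (392 ± 1.95) and EEF1A1 (307 ± 7.57) down to EIF3C (2.60 ± 0.0354), a gene with a near-identical copy whose value is therefore uncertain. Splicing factors had a median of 65.2, with all 29 above the median gene, led by SRSF3 (207 ± 10.5), DDX5 (152 ± 2.94) and HNRNPA1 (144 ± 7.35), and lowest for SF3A1 (13.955 ± 0.757). Housekeeping genes had a median of 67.0, with ACTB and EEF1A1 at the top and HPRT1 at 6.50 ± 1.42. Heat shock and chaperone genes had a median of 43.5, with HSPA8 at 362 ± 5.78, HSP90AB1 at 188 ± 6.55 and HSPB1 at 107 ± 4.26. HSPA1A, which has a near-identical copy, was the lowest at 5.61 ± 1.12. Each of these 6 medians lay above all 10000 random lists.

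The RNA polymerase II, glycolysis, cholesterol synthesis and m6A lists had lower medians, from 14.8 to 22.03. Of these, polymerase II and glycolysis genes were called high. All 42 polymerase II and elongation genes were measured (median 22.03, percentile 99.99), with HEXIM1, the inhibitor of the elongation kinase P-TEFb, at 227 ± 10.1, POLR2L at 149 ± 0.834, POLR2H at 78.1 ± 1.12 and MED14 at 4.71 ± 0.177. The glycolysis list had a median of 20.4 (percentile 98.4, 20 of 20 measured), led by GAPDH (239 ± 8.23), PKM (190 ± 0.820) and ENO1 (109 ± 6.66), with PDK1 at 6.51 ± 1.51. Cholesterol synthesis genes were not called (median 17.4, percentile 93.8). FDPS was at 116 ± 5.88 and IDI1 at 55.9 ± 3.46. The m6A methylation machinery was not called either (median 14.8, percentile 80.8, 17 of 19 measured), with the methyltransferase gene METTL3 at 52.0 ± 2.22, RBM15 at 41.0 ± 3.85, YTHDC1 at 34.5 ± 5.70 and the demethylase gene FTO at 4.08 ± 0.495.

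Proliferation genes were transcribed in these cultures. The 15 measured replication-dependent histone genes, of 26 in the list, had a median FPKM of 335, 28.6 times the median gene, with H1-2 at 549.6 ± 44.9, H4C3 at 505 ± 22.9, H2AC11 at 447 ± 38.8 and H2AC7 at 28.0 ± 2.55. Histone genes are short and repeated, and identifiers without a current symbol may hold others of them. All 24 G2/M genes had values, with a median of 23.7 (percentile 99.9). The mitotic activator CDC20 (102 ± 3.96), the kinase gene AURKB (95.0 ± 10.2) and BIRC5 (71.6 ± 5.57) were highest and CENPE lowest (4.22 ± 0.240). All 24 G1/S genes had values too, with a median of 18.3 that was not called (percentile 97.0), although it was with library b left out (97.72) and with list means (97.66), but not with library a left out (97.4). CDC6 (86.3 ± 5.03), PCNA (72.5 ± 1.55) and MCM7 (58.2 ± 3.79) led it, and CCNE1 was lowest at 3.21 ± 0.410. The G1/S median was 1.29-fold below that of G2/M, a log2 difference of -0.36 (-0.41 in library a, -0.28 in library b) that was not called (percentile 21.2).

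Immediate early genes, which respond within minutes to serum and stress, had a median of 65.4, 5.59 times the median gene, and 27 of 30 were measured. Their levels ranged widely, from CCN1, the phosphatase gene DUSP1 (636.5 ± 61.8) and IER3 (258 ± 15.5) to the nuclear receptor gene NR4A1 (3.75 ± 0.290). Targets of YAP and TGF-beta had a median of 36.6 over 16 of 17 genes, led by CCN1, ID1 and ID3, with TGFBI lowest. Both lists lay above all random lists. Genes of the unfolded protein and amino acid responses had a median of 24.3 (percentile 99.9), with the transcription factor genes ATF4 at 217 ± 24.8 and DDIT3 at 199 ± 3.05, DDIT4 at 167 ± 6.29 and VLDLR at 6.81 ± 0.983. Secretory genes of senescence were not called (median 16.6, percentile 83.9, or 48.5 with list means, 11 of 21 measured). GDF15 was at 62.6 ± 16.2, CCL2 at 49.7 ± 5.15, IGFBP7 at 41.8 ± 3.40 and LIF at 1.67 ± 0.311. Immediate early genes exceeded them 3.93-fold (percentile 99.9). Interferon response genes were not called (median 8.59, percentile 11.3, or 7.5 without library a and 19.7 without library b, 16 of 22 measured), with STAT2 at 37.99 ± 0.665, IFI6 at 19.8 ± 4.39 and IFIH1 at 1.75 ± 0.332.

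HOX genes, whose expression records the position of a fibroblast along the body axes, were measured from both ends of the clusters. Of the posterior list 9 of 16 were measured, with HOXA11 at 63.5 ± 3.58, HOXA9 at 37.1 ± 3.30, HOXA10 at 27.3 ± 1.22 and HOXD11 at 3.42 ± 0.636. Of the anterior list 6 of 23 were measured (percentile 0.06 for that number), with HOXA7 at 14.7 ± 0.509, HOXA2 at 9.77 ± 1.60, HOXD8 at 8.59 ± 0.332 and HOXC6 at 3.33 ± 0.742. The medians were 21.7 and 7.91, and the log2 difference of -1.45 (-1.44 in library a, -1.47 in library b) was not called (percentile 3.84, or 8.95 with list means). The lists of 29 long noncoding RNAs and of 20 small nuclear and polymerase III RNAs had no measured members, so these classes are not analysed here.

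Related genes were compared within each library. In each of the 13 pairs shown the log2 ratio exceeded 2 SD over the libraries and had the same sign in both. Random pairs of genes were not examined, so this shows only that the ratios exceeded the spread between libraries. COL1A1 stood 1.84-fold above COL1A2 (log2 ratio 0.88 ± 0.0761), whereas COL5A1 (26.0 ± 3.15) was 2.10-fold below COL5A2 (54.6 ± 2.54). JUN (149 ± 1.73) was 24.9-fold above FOS (5.92 ± 0.601), FOSL1 (115 ± 5.13) 3.06-fold above FOSL2 (37.7 ± 5.14) and CCN1 7.04-fold above CCN2 (169 ± 1.57). Among cell cycle regulators, CDKN1A (121 ± 5.78) was 18.6-fold above CDKN2A (6.44 ± 0.226), CDK4 (77.2 ± 12.03) 5.16-fold above CDK6 (14.8 ± 0.559) and MDM2 (28.1 ± 0.806) 2.81-fold above MDM4 (9.96 ± 0.170). TGFB1 (34.4 ± 3.52) was 7.77-fold above TGFB2 (4.34 ± 0.467) and YAP1 (15.1 ± 0.247) 1.39-fold above WWTR1 (10.9 ± 0.834). METTL3 was 1.63-fold above METTL14 (31.9 ± 2.503), FTO 3.86-fold below ALKBH5 (16.0 ± 1.51) and ACTB 1.88-fold below ACTG1. CCND1 was at 86.2 ± 2.70, and its planned partner CCND2 had no value. Folds between genes are on the log2(FPKM + 0.1) scale and depend on the gene length used in the FPKM, which is not given in the sources used here.

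**Figure D3:**
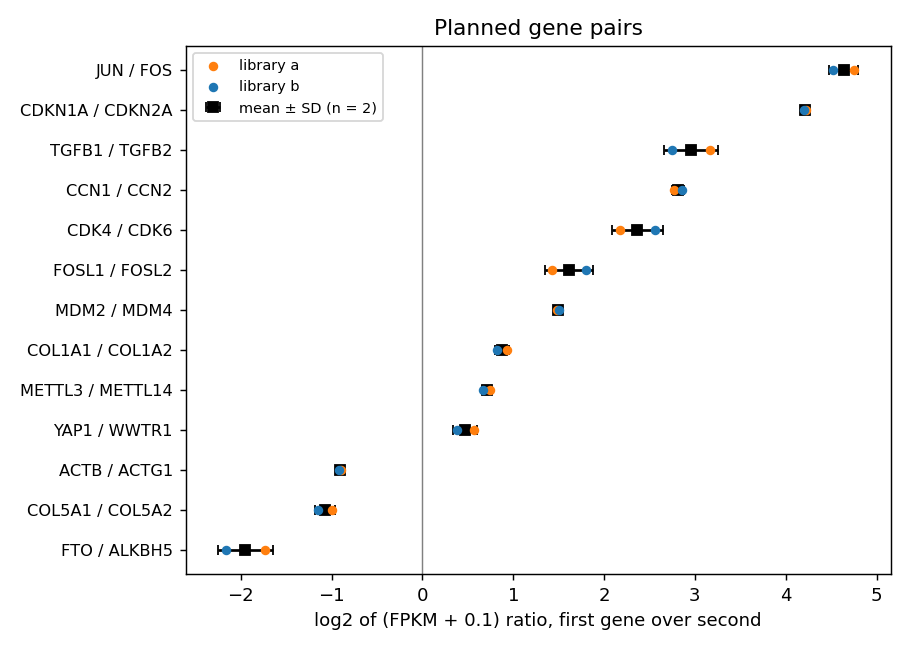
Log2 ratio of FPKM + 0.1 between the first and the second gene of each planned pair (x axis), in library a (orange), in library b (blue) and as mean ± SD over both (black, n = 2). The libraries lie on the same side of 0 in the 13 pairs shown, from 4.64 for JUN over FOS to -1.95 for FTO over ALKBH5.

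Measured genes next to each other on a chromosome had related FPKM values. Genes without a value may lie between them. Across 12063 pairs of adjacent measured genes, ordered by a GRCh38 annotation, the Spearman rho of their levels was 0.206, while the highest of 1000 shuffles of the levels over genes gave 0.0278. Pairs are not independent replicates, and rho was 0.205 and 0.206 in the libraries taken singly. The shuffles cannot tell related transcription from reads of a gene being counted to its neighbour. The use of strand in the counting is not given, and the cause of the correlation was not tested.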

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

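Each library taken alone, pseudocounts of 0.01 and 1, a minimum mean FPKM of 1 (which removed 67 genes), quantile normalization and list means were tried. A minimum of 0.1 removed no gene and tests nothing, and averaging of repeated symbols had nothing to act on. The relation to gene length and the division of neighbouring genes by strand were not run, for want of lengths on hg19 and of strands. Of 31 list levels, 28 kept their call under every setting, as did 7 of 9 contrasts. Of 31 differences between libraries, which need both libraries, 27 kept their call under the other settings. Among levels, G1/S genes reached percentile 97.66 with list means and lay between 97.4 and 97.72 in single libraries, against 97.02 for both. Epithelial and keratinocyte genes, at 2.58, came to 2.06 without library b and 3.30 without library a, but to 8.99 with list means and 18.285 with a minimum mean FPKM of 1, which removes FLG. Melanocyte genes, at 3.18, came to 2.01 without library b, 5.005 without library a and 6.93 with list means. The epithelial and melanocyte lists were each called low in library a alone, where G1/S genes were called high. Interferon response genes, at 11.3, came to 7.5 without library a and 19.7 without library b and were not called in either. With list means, mesenchymal over leukocyte genes (log2 difference 1.77) was called high and matrix against housekeeping genes (-0.76) was no longer called low. For differences between libraries, list means ended the calls of contractile (-0.036) and histone genes (0.118) and added ribosomal proteins (0.097) and splicing factors (-0.023). Quantile normalization brought the histone difference to 0.0049. The cause was not tested, except that quantile normalization by construction removes any difference tied to level. Of the gene pairs, MDM2 over MDM4 (1.41), CDKN1A over CDKN2A (4.04) and JUN over FOS (4.45) moved by more than 1 SD with a pseudocount of 1, and CDKN1A over CDKN2A (4.23) with 0.01. The correlation of neighbours kept its value within the limit set for it. So did the count of genes at FPKM 1 or more. It was 12342 with a threshold of 0.5 and 11791 with 2, and its limit was wide. The limit for the shares of the highest genes was the SD of the 2 libraries. A single library cannot lie further than that from their mean, so this tests nothing. A rank correlation does not change with the pseudocount, so only the minimum mean FPKM of 1 tested the replicate agreement (rho 0.986). No paired analysis was possible because the series has 1 group. The unknown depth limits all statements on genes with low values.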

Other observations

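Several gene families defined by their symbols, chosen after the data were seen, add to the picture of these fibroblasts. Mitochondrial ribosomal proteins (73 of 77 measured, median FPKM 22.3), proteasome subunits (36 of 39, median 30.8) and tubulins (15 of 22, median 40.0) were each at percentile 100 among random lists of their size. Their highest members were MRPL53 (146 ± 2.60, SD, n = 2), PSMB10 (134 ± 13.5) and TUBA1B (171 ± 6.03). Replacement and variant histones were also high (9 of 9, median 54.4, percentile 100), led by H3-3B (264 ± 3.15) and H2AZ1 (136 ± 8.53). All 4 ID genes were measured, from ID1 and ID3 to ID2 (149 ± 5.31) and ID4 (7.36 ± 0.841). Metallothionein genes MT2A (246 ± 18.99) and MT1E (154 ± 27.8) led a family with 3 of 9 measured (median 153.6, percentile 99.96), although members of this family resemble each other closely, so their values are uncertain.

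Among other families the levels differed, and 3 were called low. ZNF zinc finger genes (436 of 509 measured) had a median of 9.48 (percentile 0.02), solute carriers (204 of 347) a median of 8.68 and protocadherins (17 of 66) a median of 3.40, both at percentile 0. Single members stood far above their family, such as the amino acid transporter gene SLC38A2 at 567 ± 16.4 and PCDH18 at 50.7 ± 5.00. The collagen chains as a whole (27 of 44 measured) had a median of 11.4, which was not called (percentile 44.9), from COL1A1 and COL1A2 down to COL4A3 (0.570 ± 0.113), whereas the matrix list fixed in advance was called high. Of 55 keratin genes 6 were measured, with a median of 33.1 that was called high (percentile 98.98), though 4 of the 6 were already in the planned epithelial list, and KRT34 stood at 36.9 ± 0.537 next to KRT18 and KRT10. WNT and FZD genes (13 of 29, median 12.3, percentile 56.5) included WNT5A (54.7 ± 5.00) and FZD2 (50.2 ± 5.97), and FGF and FGFR genes (6 of 26, median 14.7, percentile 62.4) included FGFR1 (24.6 ± 2.33) and FGF5 (22.9 ± 0.863). Neither family was called, nor were RAB GTPases (48 of 63, median 11.6, percentile 48.4), integrins (21 of 27, median 8.40, percentile 9.44), DUSP phosphatases (16 of 23, median 18.7, percentile 95.4) and cyclin-dependent kinase inhibitors (6 of 7, median 30.2, percentile 91.0).

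The remaining tests weigh explanations for 3 patterns. Those on the mitochondrial genes and on the number of near-identical copies with a value were chosen after the result was seen.

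Mitochondrial genes were the highest in the table. Among the 11 measured heavy-strand genes the highest exceeded the lowest 6.93-fold (6.96 in library a, 6.91 in library b). One common transcript counted evenly would give about equal levels, so the spread argues against the 2 assumptions as a pair, but it does not show which of them fails. MT-ND6, alone on the light strand, lay 0.148 SD outside the range set by its neighbours MT-ND5 and MT-CYB. That is what counting without regard to strand may give, but strong light-strand transcription would give a high value too, so both stay open. The design offers no biological contrast to test, and mitochondria carried along with the nuclei were not tested.

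WDR74 was the highest nuclear gene, and its annotated span holds RNU2-2, a U2 small nuclear RNA gene that has no value under its name here. A candidate explanation is that reads from RNU2-2 were counted to WDR74. As a class, the 28 measured genes whose span holds a small nuclear RNA gene had a median of 11.9 (percentile 52.75), so the class did not stand apart. The next highest of them was C12orf57 at 308. Genes whose span holds a small nucleolar RNA (401 genes, percentile 91.1), tRNA (22, 90.2) or microRNA gene (787, 4.285) were not called either. The small nucleolar RNA class was led by EIF4A2, HSPA8 and RPL12, for which such reads were not tested singly. Whether the small RNA genes lie in introns or exons was not examined, and the question stays open for WDR74 itself. No biological explanation was tested.

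EIF3C and HSPA1A, which have near-identical copies, were the lowest of their lists, with HSPA1B at 44.7 against 5.61 for HSPA1A (HSPA1B was chosen after its value was seen). A candidate explanation is that reads fitting several copies were lost, split or left out. Of 47 other genes with near-identical copies, listed without those already seen to have a value, only FAM72A had one, 2.82 ± 0.834, while random lists of 47 protein-coding genes had at least 15 (percentile 0). With EIF3C, HSPA1A, HSPA1B and NOMO1 added, 5 of 51 had a value, against at least 16 in random lists (percentile 0). A shortage of such genes does not show why EIF3C and HSPA1A, which are present, are low, so the question stays open. The level itself cannot be judged from 1 gene (percentile 7.1). Copies that fibroblasts hardly transcribe, and members under identifiers with no current symbol, may account for part of the gap, and no biological explanation was tested.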
